A study of Mus musculus with 2 samples.

How the data were processed

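Olfactory epithelium of a male C57BL/6 mouse, treated by unilateral naris occlusion at postnatal day 14, was sampled at postnatal day 28 from the closed and the open side, 1 library per side. Per the labels, frozen dissociated cells went through dead cell removal and the Chromium 3' v3 kit, with a targeted capture of 10000 per sample, and the labels describe a single mouse. Per the submitters' processing notes, reads were processed with Cell Ranger 3.0.2 on mm10. The deposited matrix holds a count of UMIs per gene and cell barcode, as integers, over 31053 genes and 12491 barcodes of both libraries, and each barcode ends in 1 or 2. Whether sequencing depth was equalised when the authors aggregated the libraries is not given in the sources used here. No label or file ties a suffix to a side. Libraries were therefore kept as library 1 and library 2, ratios are library 2 over library 1, and no gene or cell measurement was used to guess a side.

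Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from the 13 mitochondrial genes. In library 1, 348 barcodes had fewer UMIs, 342 fewer genes and 1294 more mitochondrial UMIs, and 1469 were removed; in library 2 the numbers were 575, 567, 2380 and 2724. Kept cells held 21444390 and 37996298 UMIs, with medians of 2295.5 and 2183 genes per cell. Doublets were called per library with scrublet at its automatic threshold. It called 7 of 8298 cells (0.0844%), under the 0.5% set beforehand as the least for a working caller, so doublets were kept. An alternative removed the 109 and 337 cells with the highest scores, from an assumed 0.8% of doublets per 1000 barcodes.

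Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without odorant receptor, mitochondrial and Xist genes, were reduced to 30 principal components. A graph of 15 exact nearest neighbours weighted by shared neighbours was clustered with the Leiden method at resolution 1.0 and seed 0, giving 37 clusters. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. A cluster was named after the class with most preset markers among its 50 leading genes, with at least 3 of them, and left unnamed where another class had more among the top 10 or where depth was low. Leaving tied clusters unnamed was added after the first cluster table had been seen. Names end in "-like", since they rest on transcripts. Class shares are given from a clustering without 1337 genes, those that differed 2-fold or more between libraries in OSN-like cells and the activity lists, so that such genes could not set class borders; this choice was made after seeing the data. Levels are from the clustering with all variable genes, unless a gene was itself among a class's leading genes.

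Levels are CPM of summed UMIs per class and library, with log2 ratios after adding 1 CPM. With 1 library per side there is no p-value, no standard error and no count of changed genes. Named genes followed a rule set before the data were examined, as were the classes, lists, filters and most alternatives. The rule took genes with at least 50 CPM in the higher library, at least 50 UMIs in all, neither receptor nor mitochondrial, and in the higher library at or above the level in kept cells outside the class. From these came the 12 largest ratios in each direction in mature and immature OSN-like cells and the 6 largest in other classes with at least 100 cells in each library. Members of preset lists could also be named. The lists were activity-raised and activity-lowered OSN genes, immediate early genes, olfactory transduction, receptor trafficking and choice, axon guidance, cilia, synapse and transmitter release, oxidative stress and xenobiotic, heat shock, unfolded protein response, apoptosis, interferon response, inflammation and mucosal defence, cell cycle, neurogenesis factors, zonal markers, and mitochondrial oxidative phosphorylation. Members at 10 CPM or more counted, and each median was placed among 10000 random lists matched on level. Lists in HBC- and GBC-like cells were outside the plan.

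Symbols starting with Olfr gave 1135 receptor features. A cell was assigned the receptor with most UMIs if it had at least 3 UMIs and at least 2 in 3 of the cell's receptor UMIs. Receptor shares were correlated over all receptor symbols, those without an assigned cell included. The first definition left those out and gave negative rank correlations, because among sparse counts a receptor kept for a cell in one library mostly has none in the other; the definition was changed after that value had been seen. Receptor genes per cell along the lineage were counted after thinning to 2000 UMIs. Of the gene IDs, 30934 (99.6%) were matched to GENCODE M21 coordinates on GRCm38, which is mm10; 36 symbols were repeats.

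Alternatives were no cell filter, at least 2500 UMIs, at most 5% mitochondrial UMIs, called doublets removed, Leiden resolutions 0.5 and 2, receptor genes kept among variable genes, median-of-ratios scaling, 5 CPM added, thinning to 2000 or 4000 UMIs or none, list members with no minimum or 50 CPM, and receptors from 2 or 5 UMIs or without the dominance rule. Removing high doublet scores, clustering without differing genes, leaving cluster 8 out of those classes, leaving out the 3 cells with most UMIs of a gene, and the first correlation definition were added after seeing the data. Median-of-ratios scaling moved B lineage-like levels by 0.17 on the log2 scale and other classes by at most 0.03. The steps were tested on simulated data with the depths of mature OSN-like cells. There 98% of 100 genes simulated 2-fold higher or lower and 96% of 100 at 4-fold came within 0.5 log2, all 24 genes picked by size had been simulated as changed, 16 of 16 unchanged lists stayed inside the middle 95% of random lists, and 100% of 891 assigned cells had the right receptor. For gene levels, the simulation drew Poisson counts per gene and library from a shared profile, with no spread between cells or libraries. It therefore checks the calculation only, and could not show picks that rest on a few cells. The limit on levels outside the class was not applied in it. The axon guidance list, which shares members with the changed list, was left out. The precision set by depth is given by the counting intervals.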

Results

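Single cells of the olfactory epithelium were profiled from a male C57BL/6 mouse whose nostril had been closed on one side at postnatal day 14, and the tissue was taken at postnatal day 28. The labels name 1 library from the closed side and 1 from the open side, so there are no replicates, and every comparison describes these 2 libraries. The deposited matrix joins both libraries under barcode suffixes 1 and 2, and nothing in the sources used here ties a suffix to a side. The libraries are therefore called library 1 and library 2, and no side of the nose is assigned to either. Library 1 held 4501 barcodes and 27212821 UMIs, with a median of 4959 UMIs per barcode. Library 2 held 7990 barcodes and 49221001 UMIs, with a median of 4692. After filtering, 3032 and 5266 cells remained, with medians of 5528 and 5139.5 UMIs per cell. Intervals are exact 95% intervals, binomial for shares and Poisson for levels in CPM (UMIs of a gene scaled to a common total per class and library), and cover counting error only.

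Which cell classes made up each library was asked first. Olfactory sensory neurons (OSNs) that were mature-like held a larger share of library 1, while immature OSN-like cells and their precursors held larger shares of library 2. With cells clustered without the genes that differed between the libraries, mature OSN-like cells were 16.0% of library 1 (14.7 to 17.4) and 10.5% of library 2 (9.69 to 11.4). Immature OSN-like cells were 11.3% (10.2 to 12.5) and 14.4% (13.5 to 15.4). Mature cells thus made up 58.7% (55.3 to 62.1) of mature plus immature OSN-like cells in library 1 and 42.1% (39.5 to 44.9) in library 2. In the clustering with all variable genes, which was set beforehand, mature cells were 14.4% (13.1 to 15.7) and 9.42% (8.64 to 10.24) and immature cells 4.68% (3.96 to 5.50) and 6.84% (6.17 to 7.55), with mature cells 75.4% (71.7 to 78.9) and 57.9% (54.6 to 61.3) of both; the directions were the same, but the immature share differed more than 2-fold between clusterings. The larger immature class held 301 cells of the unnamed cluster 5 and 255 of cluster 8, a mixed cluster at high UMI counts. Without cluster 8, immature cells were 8.05% (7.10 to 9.07) and 11.4% (10.6 to 12.3), and mature cells 66.6% (63.0 to 69.99) and 47.9% (45.0 to 50.8) of both. Globose basal cell (GBC)-like cells, the dividing progenitors, were 5.31% (4.54 to 6.17) and 7.44% (6.75 to 8.19). Intermediate neuronal precursor (INP)-like cells were 1.75% (1.31 to 2.28) and 2.75% (2.33 to 3.23).

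Blood and marrow classes were also more frequent in library 2. Together, neutrophil-, B lineage-, T/NK- and macrophage/monocyte-like cells were 10.7% (9.61 to 11.8) of library 1 and 17.8% (16.8 to 18.9) of library 2. Neutrophil-like cells were 1.85% (1.40 to 2.39) and 4.69% (4.14 to 5.30), and B lineage-like cells 4.49% (3.78 to 5.28) and 7.60% (6.89 to 8.34). Sustentacular-like cells, the supporting cells of the epithelium, were 24.5% (23.0 to 26.1) of library 1 and 19.2% (18.1 to 20.3) of library 2. Horizontal basal cell (HBC)-like cells, the reserve stem cells, were 10.8% (9.73 to 11.98) and 8.68% (7.93 to 9.47). Ionocyte-like microvillous cells had nearly equal shares, 1.72% (1.28 to 2.24) and 1.71% (1.38 to 2.10). Unnamed clusters held 10.8% (9.70 to 11.9) and 11.1% (10.3 to 11.97). With all variable genes clustered, they included clusters 22, 32 and 35, which had too few preset markers for a name. Cluster 22, led by Il1b and with a neutrophil marker, was 1.39% of library 1 and 1.25% of library 2. Clusters 32, led by H2-Eb1, and 35, with Siglech, were 0.495% and 0.0989% of library 1 and 0.570% and 0.456% of library 2. The blood and marrow classes there leave these clusters out, and counting cluster 22 as neutrophil-like would narrow that contrast. Each library's shares add to a whole, so a larger share of one class lowers the others, and dead cell removal and freezing, per the labels, came before capture.

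**Figure D1:**
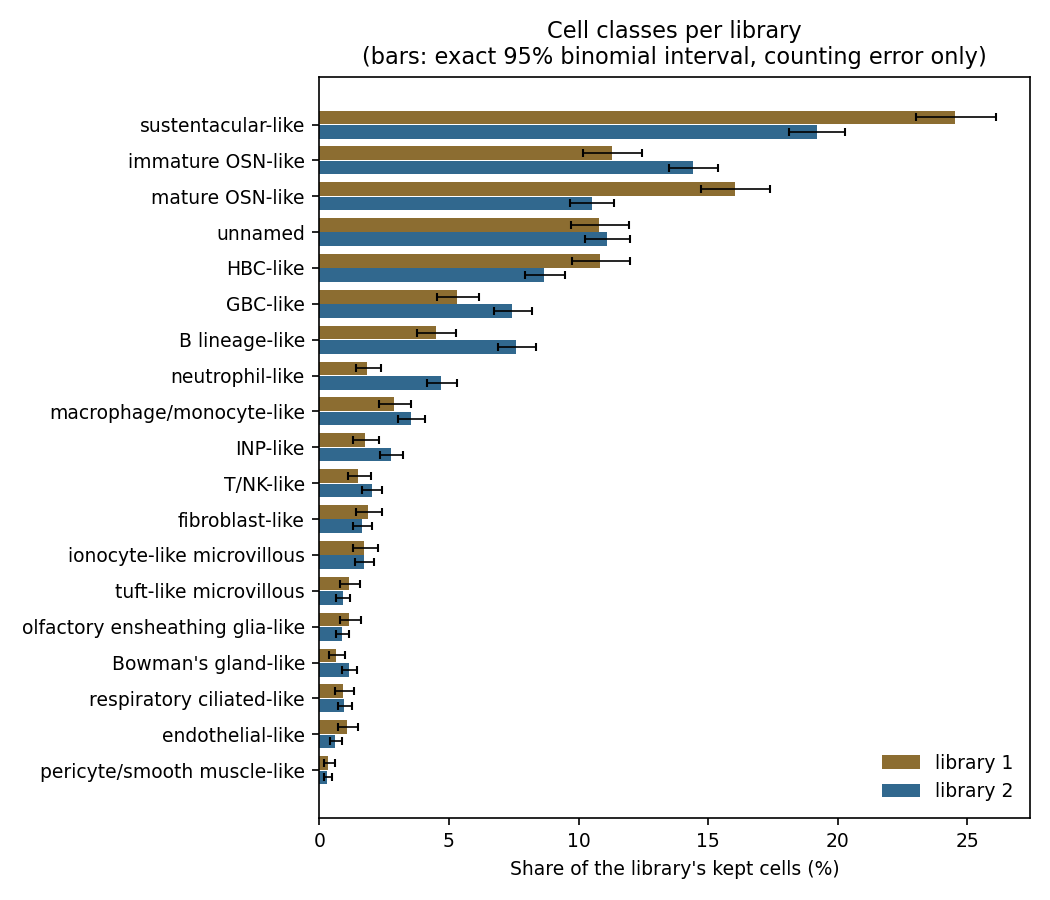
Share of each library's kept cells (%) per named class, clustered without the genes that differed between the libraries; bars show library 1 and library 2 and error bars exact 95% binomial intervals, counting error only. Mature OSN-like cells were 16.0% of library 1 and 10.5% of library 2, and immature OSN-like cells 11.3% and 14.4%. The immature class shown includes 255 cells of the mixed cluster 8. Without that cluster the immature shares were 8.05% and 11.4%.

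The order in which odorant receptor transcripts appear along the neuronal lineage was then followed over pooled cells of both libraries, each thinned to 2000 UMIs. Receptor transcripts were near background in GBC- and INP-like cells, appeared as low mixtures in cluster 11, and came from a single dominant gene in OSN-like cells. Cluster 11 was left unnamed because its leading genes held 3 markers of INPs and 3 of immature OSNs. A receptor gene was seen in 9.13% of GBC-like cells (6.78 to 11.95), 9.18% of INP-like cells (5.53 to 14.1) and 67.5% of cluster 11 cells (60.7 to 73.7), against 11.5% in sustentacular-like cells, which should lack them. The share was 83.2% in immature OSN-like cells, 92.8% in the unnamed cluster 5, which held leading genes of both OSN stages, and 96.1% in mature OSN-like cells. Cells with 2 or more receptor genes were 46.2% of cluster 11 (39.4 to 53.2), 19.4% of immature OSN-like cells (15.9 to 23.2), 15.1% of cluster 5 (11.8 to 19.0) and 8.63% of mature OSN-like cells (6.89 to 10.6). For a cell that already holds its own receptor, the background for a second gene is the share of sustentacular-like cells with any receptor gene, 11.5%, so the mature value is not above background. The interval of cluster 5 overlaps that of this background (9.97 to 13.1). The same order held within each library, at 39.0%, 20.4% and 9.03% for cluster 11, immature and mature OSN-like cells of library 1 and at 49.0%, 18.9% and 8.28% in library 2.

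Dominance of a single receptor rose along the same order. Among cells with at least 2 receptor UMIs, the top receptor held on average 45.1% of them in cluster 11, 91.7% in immature OSN-like cells, 97.3% in cluster 5 and 99.0% in mature OSN-like cells. Mean receptor UMIs per cell went from 1.958 in cluster 11 to 8.34, 17.2 and 21.3 over those stages. Without thinning, cells with 2 or more receptor genes were 65.0% of cluster 11, 33.5% of immature OSN-like cells, 27.8% of cluster 5 and 19.0% of mature OSN-like cells, against 32.0% of sustentacular-like cells with any receptor gene. In that setting only cluster 11 stood clearly above the background. Median depths were 4485 UMIs in cluster 11, 4866.5 in immature OSN-like, 5397 in cluster 5, 4962 in mature OSN-like and 6230.0 in sustentacular-like cells. Thinning left out 11, 27, 7, 17 and 66 shallower cells of these groups. When a receptor was counted only from 2 UMIs, cells with 2 or more receptor genes fell to 0.943% of cluster 11, below the 6.74% of immature OSN-like cells, so that the mixtures of cluster 11 rested on receptors with single UMIs.

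**Figure D2:**
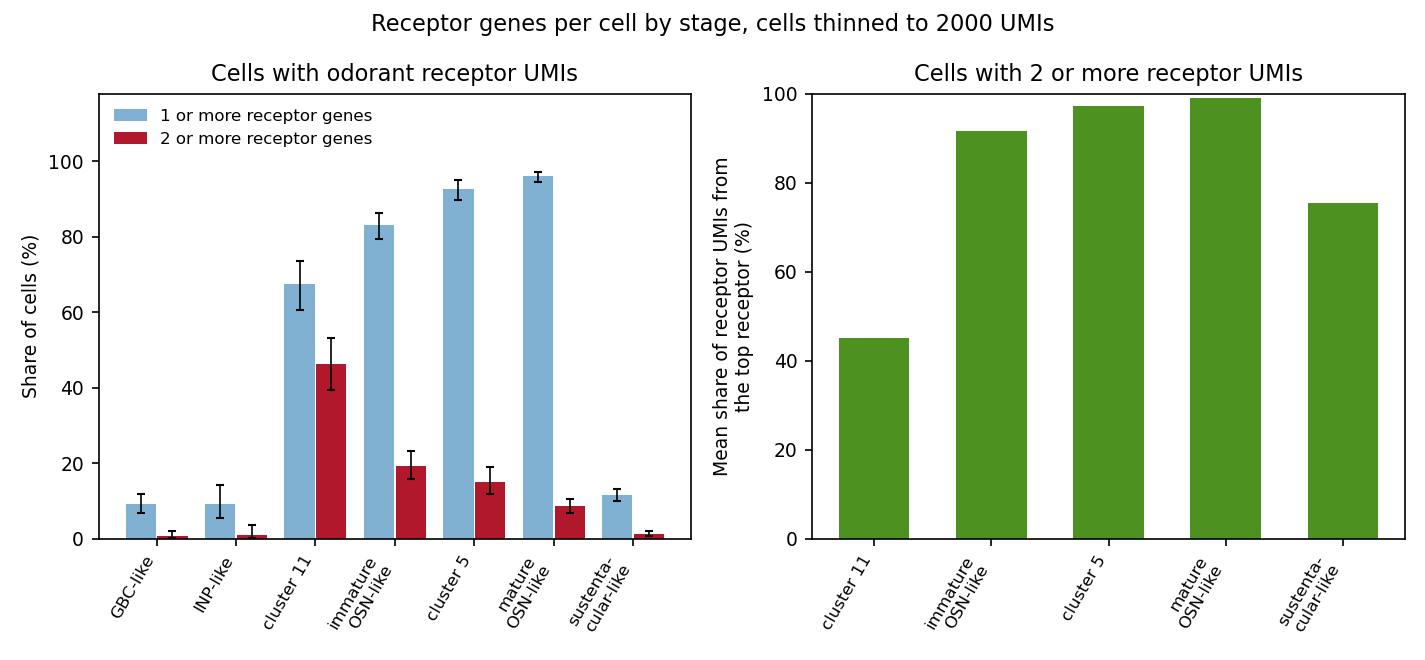
Left, share of cells (%) with 1 or more and with 2 or more odorant receptor genes by stage, cells of both libraries thinned to 2000 UMIs, with exact 95% binomial intervals as error bars; right, mean share (%) of receptor UMIs held by the top receptor in cells with at least 2 receptor UMIs. Cells with 2 or more receptor genes went from 46.2% in cluster 11 to 8.63% in mature OSN-like cells, while the top receptor's share went from 45.1% to 99.0%.

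Gene groups moved with these stages. Unfolded protein response genes, which include the stress regulators through which receptor expression is thought to feed back on receptor choice, were higher in immature OSN-like cells than in cluster 11 for 11 of 11 measured members in the pooled cells and in each library, with a median log2 difference of 1.94. Ddit3, a stress-induced transcription factor, went from 18.9 to 192 CPM, and Herpud1, a component of endoplasmic reticulum quality control, from 47.8 to 389.8 CPM. The pseudokinase gene Trib3 went from 5.41 to 73.2 CPM, and the chaperone genes Dnajb9 and Hspa5 from 54.1 to 230.5 and from 107 to 277 CPM. From immature to mature OSN-like cells, 10 of the 11 members were lower, with a median of -0.60. Kdm1a, the lysine demethylase LSD1, stood at 514 CPM in INP-like cells, 335 in cluster 11, 252 in immature and 84.5 in mature OSN-like cells. Cilia genes were higher in mature than in immature OSN-like cells for 14 of 14 members, 12 of them in each library, with a median of 0.85, as the small GTPase gene Arl3 went from 247 to 537 CPM. Synapse genes were higher for 10 of 11 members from cluster 11 to immature cells and for 11 of 12 from immature to mature cells in pooled cells, and in each library for 8 and 7 of them. Snap25 was at 35.4, 168 and 418 CPM over these stages in library 2; in library 1 it was at 53.3, 362 and 377 CPM, but 3 cells held 56.0% of its UMIs at the immature stage. Axon guidance genes went both ways, with 13 of 19 higher in mature than in immature cells.

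The receptor repertoire was read from cells in which a single receptor gene dominated. In mature OSN-like cells 887 of the cells had such a receptor, 411 in library 1 (94.3%) and 476 in library 2 (96.0%). They used 435 receptor genes, all annotated as protein coding, of which 263 were seen in library 1, 302 in library 2 and 130 in both. Single cells carried 237 of these receptors, and the 20 most frequent receptors together held 16.9% of the cells. Olfr1211 (ENSMUSG00000075112, chromosome 2, 88926876 to 88938111 in mm10) was assigned to 7 cells of library 1, 1.70% (0.687 to 3.48), and 3 cells of library 2, 0.630% (0.130 to 1.83). Olfr1260 (ENSMUSG00000042894, chromosome 2, 89974340 to 89981586) had 6 and 4 cells, and Olfr728 (ENSMUSG00000050030, chromosome 14, 50133758 to 50142680) 3 and 7 cells. Next came Olfr1264, Olfr1301 and Olfr6 with 6 and 3 cells each, and Olfr1348 with 5 and 4.

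Immature OSN-like cells with an assigned receptor numbered 94 in library 1 and 252 in library 2 and used 237 receptors, 35 of them in both libraries. Across all 1134 receptor symbols, which are genes and not replicates, shares in mature cells of the 2 libraries had Pearson's r of 0.428 and Spearman's rho of 0.328, and in immature cells 0.276 and 0.205. Only 435 symbols had an assigned mature cell and 237 an assigned immature cell. These values therefore also reflect which receptors were seen at all, not only how often. Pooled mature and immature shares had r of 0.345 and rho of 0.265, with 141 of 531 receptors seen at both stages. No receptor reached 20 assigned mature cells, the minimum set for naming receptors by their ratio between libraries. Of the preset receptors, Olfr827 (ENSMUSG00000045559) was assigned to 0 of 411 mature cells of library 1 (0 to 0.894%) and to 4 of 476 in library 2, 0.840% (0.229 to 2.14), and among all kept cells to 2 and 4. Olfr1440 (ENSMUSG00000046650) had 0 and 4 such cells, and 0 and 8 among all kept cells. Olfr1507, an abundant receptor gene, had 2 and 4 mature cells, and Olfr2 2 and 1. Olfr1325, Olfr16, Olfr73, Olfr160, Olfr90 and Olfr713 had none in any class, and Olfr151 was not analysed here.

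How gene levels in mature OSN-like cells differed between the libraries was the central comparison. Genes whose level in OSNs follows odour-driven activity were higher in library 2. S100a5, a calcium-binding protein gene induced by activity (ENSMUSG00000001023, chromosome 3, 90608523 to 90611780), was at 1972 CPM in library 1 (1918 to 2027) and 15339 CPM in library 2 (15191 to 15487) in cells grouped without differing genes, a log2 ratio of 2.96. Pcp4l1 (ENSMUSG00000038370, chromosome 1, 171173262 to 171196268), a relative of a calmodulin regulator, was at 289.7 CPM (268 to 313) and 1649 CPM (1598 to 1701). Kirrel2, an adhesion molecule of OSN axons (ENSMUSG00000036915, chromosome 7, 30447534 to 30457690), was at 39.9 CPM (32.2 to 49.0) and 226 CPM (207 to 246), and Lrrc3b at 44.3 CPM (36.1 to 53.9) and 154 CPM (139 to 171). Rasgrp4 had 2 UMIs in library 1, 0.878 CPM (0.106 to 3.17), and was at 23.9 CPM (18.1 to 30.98) in library 2.

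The activity-raised list had a median log2 ratio of 2.47, with 6 of 7 measured members higher in library 2, above all 10000 matched random lists (percentile 100; middle 95% from -0.22 to 0.17). Cidea was the member at lower level in library 2, 184 and 159 CPM. In sustentacular-like cells, where free RNA would show, S100a5 was at 25.4 CPM (21.4 to 29.9) and 103 CPM (96.6 to 110.3). Other genes named by size and higher in library 2 were the synaptic scaffold gene Dlg2 (33.4 and 122 CPM), the transcription factor gene Etv5 (15.4 and 54.1), 5730403I07Rik (31.6 and 99.0), the protease gene Pappa (16.2 and 51.6) and the splicing regulator gene Celf3 (29.8 and 74.7). Avp, Gm13757 and Hbb-bt also passed, with 79.7%, 64.0% and 100% of their library 2 UMIs in 3 cells.

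Calb2, which encodes the calcium buffer calretinin, led the named genes of high level in the other direction (ENSMUSG00000003657, chromosome 8, 110137502 to 110168210). Its level was 1501 CPM in library 1 (1451 to 1552) and 479 CPM in library 2 (452 to 508), a log2 ratio of -1.65. Kirrel3, a homophilic adhesion molecule related to Kirrel2 (ENSMUSG00000032036, chromosome 9, 34485894 to 35036716), was at 154 CPM (138.8 to 171.5) and 65.0 CPM (55.2 to 76.1). The calcium sensor gene Scgn was at 103 CPM (90.4 to 117) and 41.1 CPM (33.4 to 50.1), and the ephrin gene Efna5 at 343 CPM (319.6 to 368) and 162 CPM (146 to 179). Kcnrg (50.5 and 13.0 CPM), the ectonucleotidase gene Entpd2 (71.5 and 28.5), the transporter gene Slco3a1 (50.03 and 20.97), Rims3 (238 and 112), Snhg11 (79.0 and 39.9) and 1700097N02Rik (67.1 and 30.2) completed the genes named by size, with Ephx4 (630.1 and 331 CPM) and AC078895.1 (508 and 235) in cells grouped without differing genes. The activity-lowered list had a median of -0.16, with Kirrel3 and Hist2h2be lower in library 2 and Plxna1 at 98.3 and 131 CPM.

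**Figure D3:**
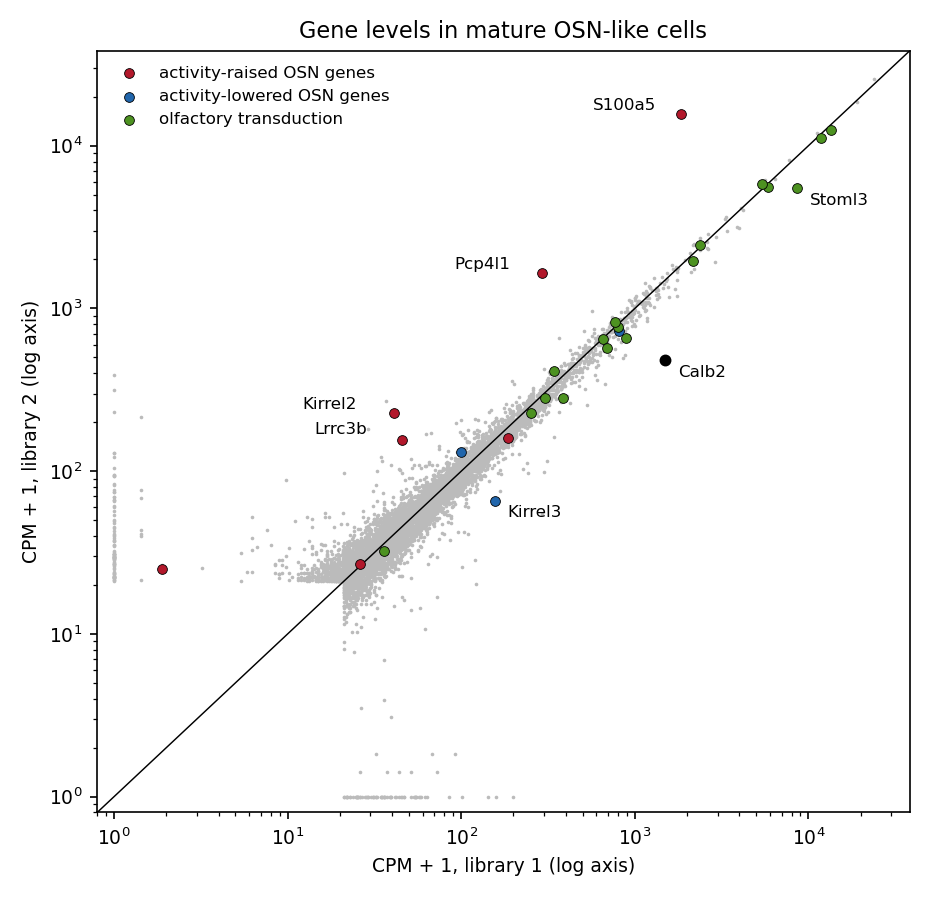
Gene levels in mature OSN-like cells, CPM plus 1 on log axes, library 1 across and library 2 upward, for genes at 20 CPM or more in either library; each point is a gene, coloured points belong to 3 preset lists, and the line marks equal levels. S100a5, Pcp4l1, Kirrel2 and Lrrc3b lie above the line, and Calb2, Kirrel3 and Stoml3 below it.

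Transduction genes differed far less. In the olfactory transduction list 13 of 17 members were higher in library 1, with a median of -0.11 at percentile 7.06. In cells grouped without differing genes, Stoml3, a membrane protein of OSN cilia, was at 8311 CPM (8199 to 8423) and 5317 CPM (5230.4 to 5405), the channel subunit gene Cnga2 at 867 CPM (831 to 904) and 639.8 CPM (609.9 to 671), and Cnga4 at 359.7 and 265 CPM. Adcy3, the adenylyl cyclase of the pathway, was at 735 and 715 CPM, and Omp at 5177 and 5696 CPM. Axon guidance genes went both ways, 11 of 20 higher in library 2, with a median of 0.04; the ephrin gene Efna3 was at 825 CPM (790.2 to 861) and 476 CPM (450.1 to 503) and the semaphorin gene Sema7a at 42.6 CPM (34.5 to 51.9) and 102 CPM (89.9 to 116). Synapse genes had a median of 0.05, with Cplx2 at 118.5 and 208 CPM and Syn2 at 34.2 and 72.6 CPM. Oxidative phosphorylation genes were higher in library 2 for 12 of 14 members by a median of 0.10, at percentile 99.7.

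The other lists in mature OSN-like cells had medians of -0.01 for receptor trafficking and choice, -0.08 for cilia, 0.01 for heat shock, -0.00 for the unfolded protein response, 0.20 for apoptosis, 0.36 for interferon response, 0.13 for neurogenesis factors and 0.01 for zonal markers. The cell cycle list had 1 measured member, Pcna, at 43.4 and 26.4 CPM. Immediate early genes had a median of 0.15 with 6 of 10 higher in library 2, among them Egr1 (124 and 206 CPM) and Nr4a1 (12.7 and 32.7), while Fos was lower (738 and 502). That median turned negative in 6 of the other settings tried, and those of the oxidative stress, apoptosis and cell cycle lists changed sign in 1 each. Oxidative stress and xenobiotic genes had a median of 0.38 and inflammation genes 1.55, but members such as Cyp2a5 (100.1 and 166 CPM) and S100a9 (5.27 and 31.9) stood far below their levels outside the class, 8104 and 7003 CPM for Cyp2a5 and 2949.5 and 5955 CPM for S100a9.

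In immature OSN-like cells the question was whether younger neurons showed the same differences. S100a5 was at 27.7 CPM (17.6 to 41.6) in library 1 and 109.8 CPM (94.6 to 127) in library 2, near the 25.4 and 103 CPM of sustentacular-like cells, so these values are at the level of free RNA and do not answer the question for S100a5. In the larger immature class formed without differing genes, which took in most of cluster 5, where S100a5 is a leading gene, it was at 411 CPM (389 to 434) and 1854 CPM (1819 to 1889). The activity-raised list had a median of 0.23 with 4 of 6 members higher in library 2, at percentile 90.4. Receptor trafficking and choice genes were higher in library 2 for 12 of 14 members, with a median of 0.34, among them the transcription factor genes Emx2 (277 and 363 CPM) and Ebf2 (508 and 646). Neurogenesis factors were higher for 10 of 11, median 0.33, with Sox11 at 1705 CPM (1617 to 1796) and 2367 CPM (2295 to 2441). Olfactory transduction genes were also higher in library 2, for 16 of 16 members with a median of 0.23, which was -0.34 in the larger class. Whether a few library 1 cells rich in other transcripts, described below, lowered these lists together was not tested. Synapse genes were higher in library 1 for 10 of 12, median -0.53, but 3 cells held 84.0% of the library 1 UMIs of Syn2 (120.6 and 15.8 CPM), and without the 3 top cells of each library the log2 ratio of Snap25 went from -1.11 to -0.21. Interferon response genes had a median of -2.00, with 5 of 5 higher in library 1, but 3 cells held 100% of the library 1 UMIs of Ifit1 and 87.5% of those of Oasl2. Inflammation genes had a median of 2.48, with 5 of 5 higher in library 2, at levels far below those outside the class, as for S100a9 (4.82 and 31.5 CPM, against 2743 and 5845). Genes named by size and higher in library 2 included the kinase genes Lats1 (30.1 and 66.6 CPM) and Wnk2 (39.8 and 75.3), the receptor gene Tgfbr1 (77.2 and 150.1), Zbtb7b (53.0 and 116), Lmtk3 (30.1 and 57.8) and B930036N10Rik (20.5 and 66.0). In the larger class formed without differing genes these differences were smaller, with Lats1 at 48.0 and 58.5 CPM and Zbtb7b at 63.4 and 85.9 CPM.

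For the genes named by size and higher in library 1, most UMIs came from the 3 cells with most UMIs of each gene; whether these were the same cells was not tested. Vip, a neuropeptide gene, had 654 UMIs in library 1 and 0 in library 2, Slc5a7, the choline transporter gene, 64 and 0, Hand2, a transcription factor gene of autonomic neurons, 63 and 0, and Nos1, which encodes neuronal nitric oxide synthase, 141 and 1. Those 3 cells held 99.8% of the Vip UMIs of library 1 and 100% of those of Slc5a7, Hand2 and Nos1; Fxyd7, Ass1, Tac2, Gfra2, Htr3a, Meg3, Lgals1 and Pmp22 had 78.4% to 100% in theirs. Medians of the transduction (0.23), oxidative stress (0.85), unfolded protein response (0.26) and interferon response (-2.00) lists changed sign in this class under other settings.

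Supporting and basal cells were compared next. In sustentacular-like cells Chil4, a chitinase-like secreted protein gene (ENSMUSG00000063779, chromosome 3, 106201490 to 106219507), had 5 UMIs in library 1, 0.887 CPM (0.288 to 2.07), and 7399 UMIs in library 2, 861 CPM (841 to 881). In cells grouped without differing genes it was at 8.56 CPM (6.31 to 11.4) and 867 CPM (847 to 887). Sult1c1, a sulfotransferase gene, was at 281 CPM (267 to 295) and 502 CPM (487 to 518) in that grouping, and its relative Sult6b1 at 220.5 CPM (208 to 233) and 124.6 CPM (117 to 132). Hykk (40.8 and 64.7 CPM), 2010007H06Rik (64.6 and 101), Ldb3 (32.5 and 51.2) and Polr2a (44.3 and 69.1) were higher in library 2, and the transcription factor genes Nfil3 (79.5 and 34.8), Irf1 (96.8 and 44.6), Atf3 (1116 and 581), Elf3 (222 and 120.4) and Csrnp1 (56.0 and 31.8) higher in library 1. The Hykk log2 ratio turned to -0.48 with at most 5% mitochondrial UMIs.

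Immediate early genes were lower in library 2 in sustentacular-like cells, for 13 of 13 members with a median of -0.30, below all 10000 matched lists. Junb was at 3347 CPM (3299.7 to 3395) and 2457 CPM (2424 to 2491), Dusp1 at 3299.7 and 2538 CPM and Nr4a3 at 20.7 and 7.91 CPM. The same list was lower for 13 of 14 members in HBC-like cells, median -0.21, and for 12 of 12 in GBC-like cells, median -0.53, with Arc at 76.7 CPM (64.4 to 90.6) and 35.1 CPM (29.7 to 41.2). Per the labels, cells were dissociated and frozen before capture. A difference in handling between the libraries was not tested and cannot be told apart from one in the tissue. Inflammation genes in GBC-like cells had a median of 3.89, with 6 of 7 higher in library 2. Levels in that class were not corrected for free RNA, and the share of these UMIs held by a few cells is not given here. Unfolded protein response genes were lower in library 2 for 8 of 9 members in sustentacular-like cells, median -0.25, and heat shock genes for 7 of 8, median -0.12. Receptor trafficking genes had a median of 0.27, which turned negative in 3 other settings, as the heat shock median turned positive in 1. Interferon genes had a median of 0.13, and the remaining lists there lay between -0.18 and 0.22, apart from the activity-raised list. That list had 2 measured members and a median of 0.99, from S100a5 alone, since Pcp4l1 stood at 304 CPM in each library.

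In HBC-like cells the sulfotransferase gene Sult1d1 was at 44.5 CPM (35.2 to 55.4) in library 1 and 338 CPM (315 to 362) in library 2, and the apolipoprotein gene Apoc1 at 189 CPM (169 to 210.4) and 405 CPM (380 to 431). Serpina3n, a protease inhibitor gene, was at 235 CPM (213 to 258) and 75.4 CPM (64.7 to 87.3), while 56.5% or more of the library 1 UMIs of Csf3, Acta2, Sprr1a and Muc5ac came from 3 cells, as did 97.7% or more of the library 2 UMIs of Ccl5 and Cxcl10. In GBC-like cells the histone gene Hist1h2ap was at 27.2 CPM (20.1 to 36.0) and 106 CPM (96.6 to 117) and Notch1 at 27.2 CPM (20.1 to 36.0) and 56.9 CPM (49.9 to 64.6), while Fdft1, of sterol synthesis, was at 65.6 and 33.9 CPM. Gm10076 was higher in library 2 in both classes (95.1 and 190.4 CPM in HBC-like, 126 and 277 in GBC-like cells). The B lineage-like class joined 3 clusters in unequal mix, with 106, 26 and 6 cells in library 1 and 230, 131 and 37 in library 2, and its cell cycle genes were higher in library 2 for 15 of 15 members, so its levels also reflect composition. Ly6a there was at 641 CPM (557 to 735) and 181 CPM (154 to 212), and all 651 library 1 UMIs of Jchain, the joining chain of secreted antibodies, came from 3 cells, against 0 in library 2.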

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

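The tests chosen only after the result was seen were, for the activity genes, free RNA, the side of the nose and the limit set for thinning, although thinning itself was chosen before the data were examined; for Chil4, all of its tests; and for cluster 8, its depth. Odorant receptor signal was present in barcodes outside the kept cells, which entered only the alternative without a cell filter. Of the barcodes removed by the cell filters, 143 of 1469 in library 1, 9.73% (8.27 to 11.4), and 138 of 2724 in library 2, 5.07% (4.27 to 5.96), carried an assigned receptor. In sustentacular-like cells, which should lack receptors, the shares were 1.88% (14 of 744) and 2.68% (27 of 1007). The removed barcodes held 112 and 113 receptors, of which 36 and 31 were not seen in kept cells of the same library.

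Activity-raised genes such as S100a5, Pcp4l1 and Kirrel2 were higher in library 2 in mature OSN-like cells. The list median was 2.62 in cells thinned to 2000 UMIs. Levels were already scaled to a common total per class and library, so thinning mostly changes how cells are weighted. That value therefore cannot decide whether depth is the cause. Free RNA is argued against: over 6 members the library difference in sustentacular-like cells was a median 0.245% of that in mature cells (-257 to 1.01, the lowest from Nrp1, at 25.02 and 26.01 CPM in mature cells). A mix of younger and older neurons is argued against by a median of 2.05 in 145 and 227 mature cells without Gap43 or Gng8 UMIs and with high Omp. None of these tests covers which receptors each library sampled, and that was not tested. Only 130 of the 435 receptors of mature cells were seen in both libraries. Activity gene levels also went with the receptor, as described below (intraclass correlation 0.543 in library 1 and 0.740 in library 2). Naris occlusion, which the design names, stays open, because 0 of the suffixes are tied to a side, and so does any difference between single libraries; a difference in odour-driven activity may underlie the pattern only as a hypothesis.

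Chil4 was found in a subset of sustentacular-like cells of library 2 and nearly absent from those of library 1 in the clustering with all variable genes. Its level in other classes of library 1 is not given here. UMIs shared with its neighbour in sequence, Chil3, are argued against by 78 Chil3 UMIs beside 7399 of Chil4, 1.05%, while cluster 24 held 2412 of Chil3 and 6 of Chil4. Free RNA is argued against by the share of library 2 cells with 3 or more Chil4 UMIs, 10.0% of sustentacular-like cells (101 of 1007; 8.24 to 12.1) and 0.202% of mature OSN-like cells (1 of 496; 0.00510 to 1.12). In library 1 it was 0 of 744 sustentacular-like cells. The top 3 cells held 19.8% of the UMIs, and without them the log2 ratio was 9.20. In cells grouped without differing genes Chil4 was at 8.56 and 867 CPM, a log2 ratio of 6.50. A patch of tissue sampled in a single library, or a difference between the sides, could give this and was not tested. Whether the Chil4 cells held RNA of secretory cells captured with them was not tested either. Bpifa1, which leads unnamed secretory clusters, was at 714 CPM in Chil4 cells and 39.3 CPM in cells without Chil4. A Bpifa1 UMI was seen in 22.8% of the Chil4 cells.

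Cluster 8 joined neuronal genes such as Gap43 and Dcx with the sustentacular gene Muc2. It had 0 genes at 50 CPM or more that were 2-fold above every other cluster, where other clusters had a median of 32 (1 to 330). Its median of 13650 UMIs was 123% of the summed medians of sustentacular-like and immature OSN-like cells, 11096.5, its median doublet score was 0.140 against 0.0207 over all cells, and 178 of its 279 cells were among the highest scores. A mix of both classes weighted by UMIs correlated with it at 0.963 over 5936 genes, and 9.94% of its library 2 cells had 3 or more Chil4 UMIs, near the share in sustentacular-like cells. Doublets of neurons and sustentacular cells are a candidate explanation, and the cluster was left unnamed; no biological explanation was tested.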

How the results depend on the processing

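Removing high doublet scores, clustering without differing genes, leaving out the 3 cells with most UMIs, leaving cluster 8 out and the first correlation definition were tests chosen only after the result was seen; results to be followed here were picked after a first table of alternatives. In every setting that gave shares, mature OSN-like cells held more of library 1, also as a share of mature plus immature cells, and blood and marrow classes more of library 2. Values below are set against the clustering with all variable genes, in which mature cells were 14.4% and 9.42% of libraries 1 and 2 and 75.4% and 57.9% of mature plus immature cells, and blood and marrow classes 10.9% and 18.3%. The activity-raised median in mature cells stayed between 2.12 and 2.74. Median-of-ratios scaling moved no list or named gene by more than its counting interval. Where values below moved or changed sign, the cause was not tested unless stated. Cluster 11 and cluster 5 have no value under other clusterings. No paired analysis was possible because no side was assigned and there is 1 library per side.

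At Leiden resolution 2, mature OSN-like cells were 18.5% and 12.3% of libraries 1 and 2, and the activity-raised median in them was 2.15. Signs changed for immediate early genes (-0.77) and oxidative stress genes (-0.50) in mature cells, transduction (-0.085) and unfolded protein response (-0.015) in immature cells, and activity-raised genes (-0.081) in sustentacular-like cells.

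With no cell filter, mature cells were 10.998% and 6.87%, blood and marrow classes 8.58% and 15.1%, and mature cells 53.0% and 38.02% of mature plus immature cells. Signs changed in immature cells for transduction (-0.24), oxidative stress (-0.036), unfolded protein response (-0.11) and Hist2h2be (-0.10), and in sustentacular-like cells for activity-raised (-0.045) and receptor trafficking genes (-0.067).

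With at least 2500 UMIs, these shares were 19.2% and 14.5%, 6.55% and 10.8%, and 65.9% and 53.4%, and the activity-raised median was 2.14. Signs changed for immediate early genes in mature cells (-0.18) and in immature cells for transduction (-0.41), unfolded protein response (-0.012) and Hist2h2be (-0.20).

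With at most 5% mitochondrial UMIs, mature cells were 24.8% and 15.6%, blood and marrow classes 17.4% and 24.8%, mature of mature plus immature cells 52.6% in library 2, the activity-raised median 2.74 and Spearman's rho of mature receptor shares 0.234. Signs changed for immediate early genes in mature cells (-0.21), interferon response in immature cells (0.14), receptor trafficking (-0.28), heat shock (0.094) and Hykk (-0.48) in sustentacular-like cells, unfolded protein response in HBC-like cells (0.046) and neurogenesis factors in GBC-like cells (-0.22). In immature cells Fxyd7 (0.72), Nos1 (0.72), Meg3 (0.012), Lgals1 (0.48) and Fxyd2 (-1.52) changed sign as well.

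Removing called doublets took out only 3 and 4 cells. Mature cells were then 15.9% and 10.6% of the libraries and 66.9% and 49.1% of mature plus immature cells. So few cells cannot cause that move by leaving. Other cells changed class on reclustering, which the counting intervals do not cover. Unfolded protein response changed sign in immature cells (-0.12). With high doublet scores removed, immediate early genes in mature cells (-0.14), receptor trafficking in HBC-like cells (-0.048) and transduction in GBC-like cells (-0.068) changed sign.

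Clustered without differing genes, mature cells were 16.0% and 10.5%, and 58.7% and 42.1% of mature plus immature cells. In immature cells transduction (-0.34), oxidative stress (-0.031), unfolded protein response (-0.010) and Hist2h2be (-0.14) changed sign; this immature class was larger, 342 and 759 cells against 142 and 360, and took in 255 cells of cluster 8. With that cluster left out of the classes, mature cells were 16.0% and 10.5% and made up 66.6% and 47.9% of mature plus immature cells.

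In cells thinned to 2000 UMIs, signs changed for immediate early genes in mature cells (-0.022), unfolded protein response (-0.011) and Hist2h2be (-0.18) in immature cells, and receptor trafficking (-0.059) and apoptosis (0.0013) in sustentacular-like cells. With no minimum level for list members, the activity-raised median was 2.12 and cell cycle in mature cells 0.28, a list with 1 member at the usual minimum. With 50 CPM, immediate early genes (-0.061) and apoptosis (-0.029) in mature cells changed sign. Without the 3 top cells, Fxyd2 in immature cells changed sign (-0.58).

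Receptor shares over receptors with an assigned cell only had Spearman's rho of -0.170 in mature and -0.410 in immature cells, negative by construction among sparse counts. Cells with 2 or more receptor genes in cluster 11, immature and mature cells were 64.2%, 30.3% and 15.02% when thinned to 4000 UMIs, 65.0%, 33.5% and 19.0% without thinning, and 0.943%, 6.74% and 1.42% when a receptor counted from 2 UMIs. In that last setting cluster 11 was the lowest of these groups and below cluster 5 (3.97%), so the order was lost. At 2000 UMIs the shares were 46.2%, 19.4% and 8.63%, so the count depends on depth in each of these groups.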

Other observations

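The thinned correlations and those without S100a5 were tests chosen only after the result was seen, as were the gene levels by receptor and in Chil4 cells. Among mature OSN-like cells, S100a5 levels went with the receptor a neuron expressed. All 6 library 1 cells and all 4 library 2 cells with Olfr1260 had S100a5, at 18070 CPM (16664 to 19562) and 29229 CPM (26522 to 32137), although the library 1 level over all mature cells was far lower. Cells with Olfr1297 had no S100a5 UMI in either library (4 and 4 cells) and held Calb2, the calretinin gene, at 2445 and 1157 CPM, while Olfr1260 cells held Calb2 at 29.6 and 0 CPM. Olfr728 cells had little S100a5 in library 1 (154 CPM, 3 cells) and none in library 2 (7 cells). For other receptors the libraries differed: Olfr6 cells were at 95.3 CPM (6 cells) and 35506 CPM (3 cells), and Olfr1348 cells at 0 (5 cells) and 5478 CPM (4 cells). In library 2, 5 cells with Olfr524 reached 62268 CPM (59430 to 65205). These receptors were picked after their values were seen.

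The other sustentacular-like cells of library 2 differed from those with Chil4 in more than that gene. Summed over the 101 Chil4 cells there was more of the secreted protein genes Bpifa1 (714 against 39.3 CPM), Obp2a (414 against 119), Obp2b (255 against 66.4) and Lcn3 (108 against 23.8). A minority of Chil4 cells carried them, 22.8% for Bpifa1, 36.6% for Obp2a and for Obp2b and 16.8% for Lcn3, and these genes also lead Bowman's gland-like or unnamed secretory clusters. The Chil4 cells had less of Sult1c1 (105 against 598), Sult6b1 (7.54 against 136) and Rgs5 (17.0 against 117.9).

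An activity score, the mean log2 level of activity-raised genes less that of activity-lowered genes in a cell, was alike in cells of the same receptor. Its intraclass correlation was 0.543 in library 1 (83 receptors, 231 cells) and 0.740 in library 2 (107 receptors, 281 cells), above the 0.1 set beforehand. After thinning it was 0.459 and 0.632, and without S100a5 0.417 and 0.636. Receptor means of the score in both libraries had Spearman's rho of 0.381 and Pearson's r of 0.389 over 130 receptors. The receptor may thus set part of a neuron's activity gene level, as a hypothesis. Cells of a receptor also share a region of the epithelium, and location was not tested and stays open.

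Chil4 cells were predicted to hold less of the sustentacular genes Cyp2g1 and Cyp2a5, with a log2 ratio under -1. The ratio was -0.31, from 24087.5 CPM in 101 Chil4 cells and 29953.3 CPM in 874 cells without the gene, so the prediction was not met.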
